A study of Mus musculus with 3 samples.

How the data were processed

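RNA from the lungs of 3 mice was hybridised to 1 Affymetrix array each, after biotin labelling, per the labels' protocols. The groups were wild type lung, mutant lung with tumour and mutant lung after macrophage depletion, with 1 array each, as the labels give them. The arrays carried 45101 probe sets, 64 of them controls.

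The deposited value table holds a linear intensity per probe set and array. The way the authors summarised and scaled those intensities is not given in the sources used here, and Partek is named, without a version, in the submitters' processing notes. The array medians were 128, 124 and 127, and the kind of scaling stays unknown. The authors also deposited 3 comparison tables that hold the ratio of each pair of samples as a linear fold, per the file headers. The ratio of a table's own comparison was never between 0.50 and 2.00, so each table holds only probe sets past 2-fold. Across listed probe sets the log2 of these ratios correlated with the log2 difference of the deposited intensities at 0.94, 0.93 and 0.90 for the 3 comparisons. Of the genes named by the rule below that were at least 2-fold apart, 50 of 178, 39 of 146 and 38 of 134 had a fold over 1.5 times that in the authors' deposited table, after the lower bounds were set. Signed fold columns in the same deposited tables were not used.

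All values in the results section are from the value table, as log2 of the intensities with no further scaling, unless the authors' deposited tables are named. Probe sets were named only through the deposited tables, which list 4310 of them (9.56%). Of these, 3858 had 1 gene symbol, 180 had several and 238 had none, and 34 were controls. Symbols were updated with the RefSeq gene table of GRCm38.p6 through the transcript accession (3661 probe sets), the current symbol (66) or an older symbol (42), and the file's name was kept for 89. This gave 2944 genes, 663 of them with more than 1 listed probe set. The naming selects genes that differed, so the shares of genes past 2-fold are not those of all genes. A list member that was not named may lack a probe set or may have differed little. No coordinates are given, because the build behind the array is not given in the sources used here.

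A gene took the value of its listed probe set with the highest mean over the arrays. Among genes at least 2-fold apart with several probe sets, all probe sets went the same way in 498 of 504, 373 of 379 and 269 of 277 genes for the 3 comparisons, in the order of the results section. A gene entered a comparison if the brighter array was at or above that array's 50th percentile. For the share of a difference absent in depleted lung, this filter applied to tumour against wild type lung only. Where the dimmer side was below the array's 25th percentile, the fold was computed against that percentile and is a lower bound. Detection calls were not used here. Counts are of genes at least 2-fold apart. No p-value was computed, since each group had 1 array. The median of each of 34 gene lists was set against 10000 random lists of named genes of the same size, matched on mean level in 20 bins.

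Named genes were the 8 highest and 8 lowest per comparison that passed the level filter, had an established symbol and had all probe sets in 1 direction. To these were added the 2 members per list with the largest differences of at least 2-fold (up to 4 for a list described in the text) and a set of genes given in any case. A gene named in 1 comparison could be given in the other two, and some genes that met the rule are not reported here. These rules, the lists and the alternatives that follow were fixed before the data were examined. The alternatives were the median over probe sets, leaving out probe sets of shared sequence, other scalings, level filters at none and the 75th percentile, a floor, thresholds of 1.5-fold and 3-fold, counting probe sets, and the authors' deposited tables. Scaling to the hybridization controls, either to equal medians of the controls or by the median over control probe sets of the difference from the wild type array, the authors' ratios for lists and genes, leaving out sex-linked genes and using all probe sets for the absent share were added after seeing the data.

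Overlaps and correlations of the comparisons with wild type were set against 3 simulated unchanged arrays of equal normal noise, with 200000 simulated genes. The steps were tested on simulated data. With 100 genes well above the level filter planted 4-fold higher and 100 planted 4-fold lower, the simulated comparison of tumour with wild type lung recovered 100 and 100 over 2425 genes and called 11 others. The simulated noise was set by hand, as the noise of the real arrays was not measured. The test therefore checks the steps and does not estimate how many real calls are noise. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.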

Results

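Gene expression was measured on 3 Affymetrix arrays, each hybridised with biotin-labelled RNA from the lung of 1 mouse aged 16 weeks. The first mouse was wild type. The second carried the IKKα mutant genotype given in the labels as KA/KA-Lori-Ikkα, and its sample mixed lung squamous cell carcinoma with tissue next to the tumour (tumour lung below). The third had the same genotype and was treated to deplete macrophages, and its lung was described as somewhat inflamed with no tumour seen (depleted lung below). IKKα is a kinase of the NF-kB pathway, encoded by Chuk. There were no replicates, so no value has an error, no test was made, and the number of arrays limits the precision. Every difference below describes these 3 arrays. The arrays had similar median intensities of 128, 124 and 127 in the order above.

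Gene names came from the authors' deposited tables, which list probe sets past 2-fold in at least 1 comparison. They named 2944 genes, and the gene lists were therefore measured only on members that differed somewhere. Chuk, Csf1r, Nkx2-1, Sftpc and Scgb1a1, which were to be given in any case, were not named there and are not analysed here. Named list members were 34 of 38 for squamous epithelium, 19 of 25 for monocytes and macrophages and 15 of 30 for the cell cycle. They were 12 of 24 for oxidative stress, 11 of 23 for NF-kB and 2 of 17 for alveolar type II cells. List counts below are shares of named members, not of whole lists. Where the dimmer array was below its 25th percentile, a difference is given as a lower bound ("at least"). The bound holds for the deposited intensities only, and where a fold was over 1.5 times that in the authors' deposited table, the latter is given too.

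The comparison of tumour lung with wild type lung addressed how the mutant lung with carcinoma differed from normal lung. Genes of squamous epithelium were far higher in the tumour lung. Of the 34 measured members of that list, 33 were at least 2-fold higher and 1 was lower, with a median log2 difference of 4.30 (3.92 with dim values raised to the 25th percentile). Krt5, a basal cell keratin, had an intensity of 7347 against 106, a 69.5-fold difference (log2 6.12), where the authors' deposited table has a log2 ratio of 4.17. Krt14, its usual partner, was at least 438-fold higher, Krt16 at least 140-fold, and Sprr1b, a cornified envelope precursor, at least 104-fold. The transcription factor Trp63 was 10.3-fold higher and Trim29 was 14.8-fold higher. The authors' deposited table has 192-fold for Krt14 and 6.30-fold for Trim29. Sox2 was the member that was lower, with 101 against 434. Keratin and Sprr genes belong to families of similar sequence, so the values of single members are uncertain.

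Most monocyte and macrophage, cytokine and neutrophil genes were also higher in the tumour lung. Of 19 measured monocyte and macrophage genes, 18 were at least 2-fold higher and none was lower, with a median log2 difference of 3.17. Cd68, a lysosomal macrophage marker, was 8.57-fold higher, Adgre1 (the F4/80 antigen) 4.42-fold, Trem2 48.3-fold and the scavenger receptor gene Cd163 27.6-fold. For Trem2 the authors' deposited table has 12.7-fold. Among 24 cytokine and chemokine genes, 19 were at least 2-fold higher and none was lower, with a median of 3.71 (3.39 with dim values raised). The monocyte attractants Ccl8 and Ccl12 were 90.9-fold and at least 91.1-fold higher, where the authors' deposited table has 41.1-fold for Ccl12. Of 13 matrix metalloproteinase and inhibitor genes, 11 were higher, led by Mmp12 (83.9-fold) and Mmp13 (51.4-fold). All 6 measured complement and acute phase genes were higher, among them Saa3 at 102-fold. Of 13 neutrophil genes 9 were higher, including S100a8 at 7.08-fold, and of 16 T cell genes 10 were higher. Of 5 dendritic cell genes 3 were higher and 1 was lower (median 1.96). Several other immune lists did not follow. Of 13 alveolar macrophage genes 7 were higher and 4 lower, and of 14 B and plasma cell genes 6 were higher and 4 lower. Both mast cell and basophil genes and both NK cell genes were lower. Of 15 cell cycle genes 14 were higher, with Mki67, a proliferation marker, at 4.51-fold. Of 10 genes of growth factors and epidermal growth factor receptor ligands, 6 were at least 2-fold higher and 2 lower. The epidermal growth factor receptor ligand Ereg was at least 16.2-fold higher (7.09-fold in the authors' deposited table), and Igf1 was 11.4-fold higher. Chil4, a chitinase-like protein gene, was 533-fold higher.

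Genes of ciliated, club and endothelial cells were lower in the tumour lung. All 12 measured ciliated cell genes were at least 2-fold lower, with a median log2 difference of -2.35. The same held for 9 of 10 club and secretory cell genes (median -2.73) and 13 of 15 endothelial genes (median -2.28), and in neither list was a gene 2-fold higher. Bpifa1, a secreted airway protein, had an intensity of 17.2 in the tumour lung against 13617, at least 383-fold lower. Tmem100 and Tek, both expressed in endothelium, were 10.9-fold and 6.55-fold lower. Of 11 alveolar type I genes 8 were lower, as were 4 of 7 smooth muscle and 5 of 6 mesothelium genes. Neither of the 2 named alveolar type II genes differed by 2-fold (median 0.35). All 10 measured cardiac and skeletal muscle genes were lower, with a median of -6.09 (-6.08 with dim values raised). Myh6, the cardiac myosin heavy chain, was at least 310-fold lower. How much heart or skeletal muscle each sample held was not measured, which limits this list in every comparison.

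**Figure D1:**
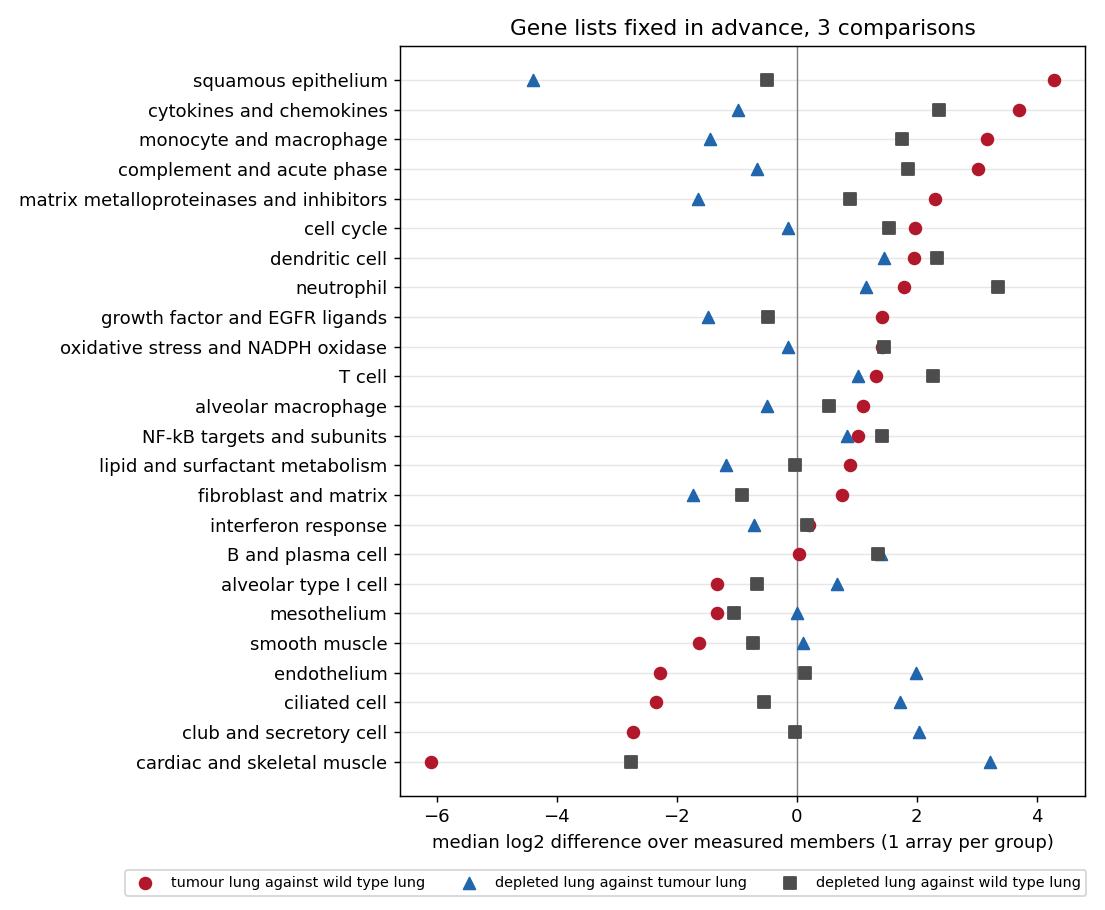
Median log2 difference (x axis) over the measured members of each gene list shown (y axis) for the 3 comparisons, with 1 array per group and no error. Lists with few measured members in any comparison and the sex-linked list are left out. The squamous list stood at 4.30 in tumour lung against wild type and at -4.40 in depleted against tumour lung, and the neutrophil list at 3.36 in depleted against wild type lung; the NF-kB and alveolar macrophage medians in tumour lung are close to 0 when scaled to the hybridization controls, at -0.11 and -0.027 with equal control medians and 0.018 and 0.10 with the median control difference removed.

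Over the 2813 named genes that passed the level filter, 1056 were at least 2-fold higher and 1074 at least 2-fold lower in the tumour lung. The squamous and macrophage medians each lay above all 10000 random lists of the same size and level, and the ciliated, club cell and endothelial medians below all of them, which describes these arrays only. The mice also differed in sex-linked genes: Xist, transcribed from the inactive X chromosome, was 83.2-fold higher in the tumour lung, and all 4 measured Y-linked genes were lower, Eif2s3y by at least 37.7-fold. The authors' deposited table has 54.1-fold for Xist and 22.7-fold for Eif2s3y. The hybridization controls were higher on the tumour array than on the wild type array by a median log2 difference of 1.00, while the medians of the controls on each array differed by 1.13. With equal control medians 422 genes were higher and 1465 lower and the median of all probe sets was -1.17, and with the median difference removed 463 were higher and 1429 lower and that median was -1.04. The T cell median of 1.33 was then 0.28 and 0.41, and the neutrophil median of 1.78 was 0.80 and 0.93. For dendritic cell genes the median of 1.96 was 0.83 and 0.96. Likewise the cell cycle median of 1.98 was 0.90 and 1.03, and the growth factor median of 1.43 was 0.30 and 0.43.

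The comparison of depleted lung with tumour lung asked what differed in mutant lung after macrophage depletion. It also compared a lung without an observed tumour with a sample containing one. Of the 34 squamous genes, 33 were at least 2-fold lower in the depleted lung and 1 was higher, with a median log2 difference of -4.40 (-3.87 with dim values raised). Krt5 was 111-fold lower, with an intensity of 66.4 against 7347. The authors' deposited table has 21.4-fold for Krt5, 197-fold for Krt14 and 3.52-fold for Trim29. Krt14 was at least 435-fold lower, Trp63 11.3-fold and Trim29 5.67-fold. Sox2 was the exception, 2.71-fold higher.

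Of the 19 monocyte and macrophage genes, 12 were at least 2-fold lower in the depleted lung, 1 was higher and 6 were under 2-fold, with a median of -1.44. The size differed between members. Cd163 was 22.5-fold lower, Mmp12 13.9-fold, Trem2 7.79-fold and Cd68 2.54-fold, while Adgre1 read 1438 against 2829 and the lipopolysaccharide co-receptor gene Cd14 read 5345 against 4565. The alveolar macrophage list went both ways, with 6 of 13 genes at least 2-fold lower and 5 higher. Marco, a scavenger receptor of macrophages, was bright only on the depleted array, with an intensity of 1289 against 12.1 in tumour lung and 8.90 in wild type lung, at least 36.3-fold above tumour lung (21.7-fold in the authors' deposited table).

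Most fibroblast, matrix and metalloproteinase genes were lower as well. Of 20 fibroblast and matrix genes 13 were at least 2-fold lower and none was higher, with a median of -1.73. The matrix protein gene Tnc was 27.1-fold lower and Col1a1 9.59-fold. Of 13 metalloproteinase and inhibitor genes 9 were lower, Mmp13 by at least 121-fold, where the authors' deposited table has 47.9-fold. Of 9 growth factor and receptor ligand genes 5 were at least 2-fold lower and 1 higher. Among them Igf1 and Ereg were 13.2-fold and at least 16.1-fold lower, with 7.09-fold for Ereg in the authors' deposited table. Cytokine and chemokine genes were split, with 12 of 25 lower and 5 higher. Ccl12 was 10.0-fold lower and Ccl7 11.7-fold, whereas Ccl17 was 5.04-fold higher and Cxcl1 3.71-fold.

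Genes of B and plasma cells, neutrophils, endothelium and airway cells were mostly higher in the depleted lung. Of 15 neutrophil genes 9 were at least 2-fold higher and 2 lower, with a median of 1.15, and the granule protein gene Ngp was 8.40-fold higher (5.57-fold in the authors' deposited table). Of 16 T cell genes 8 were higher and none was lower, with Cd3d, part of the T cell receptor complex, at 3.52-fold. Of 14 B and plasma cell genes 8 were higher and 1 lower, with a median of 1.40. Of 15 endothelial genes 13 were higher (median 1.99), as were 10 of 12 ciliated genes (median 1.72) and 9 of 10 club and secretory genes (median 2.04). Other lung lists did not follow: 3 of 11 alveolar type I genes and 3 of 7 smooth muscle genes were higher, and both named alveolar type II genes were lower (median -1.79). Cldn5, a tight junction gene of endothelium, was 8.79-fold higher and Bpifa1 at least 86.7-fold. None of the 15 cell cycle genes differed by 2-fold, and Mki67 had an intensity of 895 against 715.

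**Figure D2:**
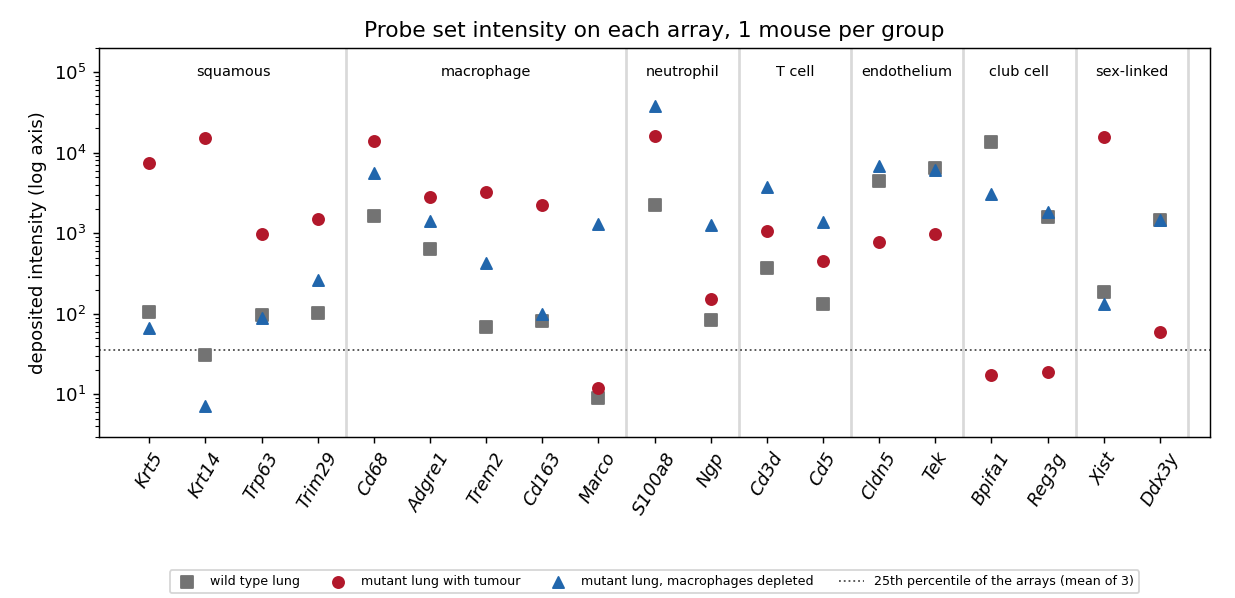
Deposited intensity (log y axis) of 1 probe set per gene on each of the 3 arrays, 1 mouse per array, with the genes on the x axis grouped by list and the mean of the arrays' 25th percentiles dotted. Krt5 read 106, 7347 and 66.4 in wild type, tumour and depleted lung, and Marco 8.90, 12.1 and 1289.

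In this comparison 810 of 2744 named genes were at least 2-fold higher in the depleted lung and 752 at least 2-fold lower. Xist was 117-fold lower in the depleted lung and Eif2s3y at least 41.3-fold higher, where the authors' deposited table has 55.7-fold and 26.4-fold. The hybridization controls of these arrays differed by a median log2 of 0.15.

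The comparison of depleted lung with wild type lung showed how far the treated mutant lung differed from normal. The sex-linked genes did not separate these arrays, as all 5 were within 2-fold. Most monocyte and macrophage, neutrophil, T cell, B cell and cytokine genes were above wild type. Of 18 monocyte and macrophage genes 15 were at least 2-fold higher and none was lower, with a median log2 difference of 1.76. Cd68 was 3.38-fold higher, Gpnmb 9.44-fold and Trem2 6.20-fold, where the authors' deposited table has 2.07-fold for Trem2. Cd163, with an intensity of 101 against 82.0, was too dim to pass the level filter and is not among the 18. Of 15 neutrophil genes 13 were higher and 1 was lower, with a median of 3.36 (3.12 with dim values raised), and S100a8 reached an intensity of 37994 against 2272. All 16 T cell genes were higher (median 2.28), with Cd3d at 10.2-fold, and 11 of 14 B and plasma cell genes were higher (median 1.36). Of 22 cytokine and chemokine genes 20 were higher, with Cxcl1 at 55.3-fold (12.2-fold in the authors' deposited table) and Ccl8 at 20.3-fold. Of 5 dendritic cell genes 3 were higher and none was lower (median 2.33). Without scaling to the hybridization controls, several other immune lists stayed nearer to wild type. Of 14 alveolar macrophage genes 4 were higher and 2 lower, and 1 of 3 class II antigen presentation genes was higher. None of 5 interferon response, 2 NK cell and 2 mast cell and basophil genes differed by 2-fold. With equal control medians the alveolar macrophage, interferon, NK cell and mast cell medians were -0.74, -1.12, -1.16 and -1.21. With the median control difference removed they were -0.64, -1.02, -1.05 and -1.11. Of 15 cell cycle genes 12 were higher, with Mki67 at 5.64-fold. Saa3 was 84.3-fold higher, and Clca1, a gene of mucous cells, was at least 41.9-fold higher.

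Without scaling to the hybridization controls, most measured squamous, endothelial and airway genes were within 2-fold of wild type. Of 34 named squamous genes 11 passed the level filter here, and 2 of them were at least 2-fold higher, 3 lower and 6 under 2-fold. Among those 11, Trim29 was 2.61-fold higher. Trp63 (87.6 against 96.5) and Krt5 (66.4 against 106) were too dim on both arrays to pass the filter. Of 15 endothelial genes 14 were under 2-fold, the exception being the receptor gene Kdr, 5.68-fold lower. Of 12 ciliated genes 11 and of 10 club and secretory genes 7 were under 2-fold. With equal control medians the endothelial, ciliated and club medians were -1.15, -1.83 and -1.32. With the median control difference removed they were -1.04, -1.73 and -1.21. Both scalings lower every probe set by 1 amount, and the median of all probe sets was then -1.31 and -1.20. The nearness of these lists to wild type therefore depended on the scaling, while their distance from the median of all probe sets did not. Of 19 fibroblast and matrix genes 8 were lower and 1 was higher, and all 10 cardiac and skeletal muscle genes were lower, with a median of -2.77. Both named alveolar type II genes (median -1.44), 5 of 11 alveolar type I genes, 3 of 7 smooth muscle genes and 3 of 6 mesothelium genes were also lower, and none in these lists was higher.

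Of 2622 named genes 644 were at least 2-fold higher in the depleted lung than in wild type and 547 at least 2-fold lower. The hybridization controls were higher on the depleted array by a median log2 of 1.18, and the control medians differed by 1.29. With equal control medians, 152 genes were higher and 1561 lower, and the macrophage median was 0.47 and the squamous median -1.87, while the median of all probe sets was -1.31. With the median difference removed, 174 genes were higher and 1487 lower, and these medians were 0.57, -1.76 and -1.20. The B and plasma cell median of 1.36 was then 0.074 and 0.18, and the cell cycle median of 1.55 was 0.32 and 0.43. Likewise the T cell median of 2.28 was 0.99 and 1.10, and the cytokine and chemokine median of 2.37 was 1.08 and 1.19. For neutrophil genes the median of 3.36 was 2.09 and 2.20, and for dendritic cell genes that of 2.33 was 1.05 and 1.15. Adgre1, 2.24-fold higher without scaling, was then close to wild type, with a log2 difference of -0.12 or -0.018.

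Of the 1056 genes higher in tumour lung than in wild type, 309 (29.3%) lay within 1.5-fold of wild type in the depleted lung, 472 were still at least 2-fold higher and 56 were at least 2-fold lower. The level filter was applied here to tumour against wild type lung only, so genes dim on both other arrays are counted. Of the 1074 genes lower in tumour lung, 440 (41.0%) lay within 1.5-fold of wild type, 336 were still at least 2-fold lower and 18 were at least 2-fold higher. The median share of the difference that was absent in the depleted lung was 56.5% for higher genes and 61.4% for lower genes. With equal medians of the hybridization controls the shares were 100.1% and 32.5%, and with the median control difference removed 97.5% and 33.1%, so their order turned. Both differences use the same wild type array, and 3 simulated arrays that differ by equal noise alone gave 49.8% and 50.3%. Equal noise fixes these shares and the simulated correlation below in advance. The real differences had unequal SDs over probe sets past the level filter, of 1.10, 0.94 and 0.77 for the 3 comparisons. The simulation therefore cannot show whether the shares, correlation or overlaps go beyond those of unchanged arrays. With genes chosen on 1 probe set and measured on another, the shares were 61.9% over 257 genes and 57.4% over 247 genes. Across 25131 probe sets the 2 differences from wild type correlated at 0.54, against 0.50 for simulated unchanged arrays; probe sets are not independent replicates. Their covariance was 0.47, with no simulated value beside it, since the noise of an array was not measured. Of 23359 probe sets measured in both, 753 were at least 2-fold higher in both mutant lungs and 761 lower in both, where independent lists would share 87.0 and 166. Simulated unchanged arrays with a shared control and as many probe sets called would share 371 and 587. The higher count covers only 1668 of the 2260 probe sets higher in tumour lung, as those dim on both other arrays were not measured in both comparisons. Part of the overlap may come from the shared array, which could not be split.

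**Figure D3:**
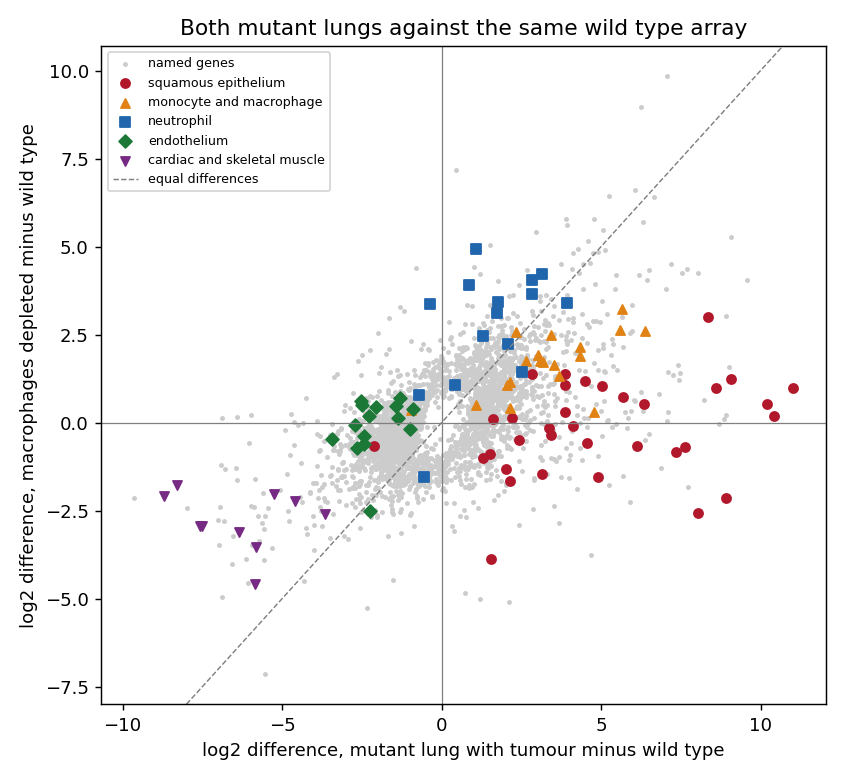
Log2 difference from the wild type array for each named gene, tumour lung on the x axis and depleted lung on the y axis, with 5 gene lists in colour and equal differences dashed. Squamous genes lay far right with a median of 4.30 on the x axis, and neutrophil genes lay high with a median of 3.36 on the y axis.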

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

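All tests in this part were chosen after the result was seen. Control probe sets, which the comparisons do not use, were brighter on both mutant arrays than on the wild type array. The hybridization controls, added to the hybridization mix, were higher by a median log2 of 1.00 in tumour lung and 1.18 in depleted lung, the poly-A controls, added to the RNA, by 1.69 and 2.38, and the 18S ribosomal RNA probe sets by 2.55 and 2.29. Arrays of unequal brightness that were scaled to equal medians may account for the hybridization controls, which moved by nearly 1 factor, with an SD over 18 probe sets of 0.12. The same factor leaves a poly-A excess of 1.20 in depleted against wild type lung, larger than the SD of 0.86 over 24 poly-A probe sets. In tumour lung the excess of 0.69 is within the SD of 0.76. These SDs describe single probe sets and not the error of a median, so they do not separate the 2 arrays. All 24 poly-A probe sets were higher on both mutant arrays than on the wild type array. The amount of poly-A control per sample stays open, and no biological explanation was tested.

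The sex-linked genes set the tumour array apart. A female tumour-bearing mouse and male mice for the other arrays is a candidate explanation, as the Y-linked gene that differed least had a log2 difference of -4.51. Loss of the Y chromosome in male tumour cells would leave Xist near wild type, whereas it was higher by 6.38. The labels give no sex. Sex and the tumour cannot be told apart as a source of the squamous difference, since the design has no second array of that sex, and the squamous list was at -0.49 in depleted against wild type lung.

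Macrophage genes were lower in depleted than in tumour lung, with a median log2 difference of -1.44. A lung of wild type composition that only lacked the tumour would put them near wild type, but their median was 1.76 above it. That value is 0.47 with equal medians of the hybridization controls, where the median of all probe sets is -1.31, and 0.57 with the median control difference removed. A uniform loss of unchanged macrophages stays open: the members' log2 differences had an SD of 1.34, but the spread between mice was not measured, and an earlier test, 5 of 13 alveolar macrophage genes at least 2-fold higher, rests partly on genes that other lung cells express. The treatment and the absence of a tumour cannot be told apart, because the only treated lung was also the only mutant lung without a tumour, with the squamous list at -0.49 against wild type.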

How the results depend on the processing

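Scaling to the hybridization controls in either form, the authors' ratios for lists and genes, leaving out sex-linked genes, using all probe sets for the absent share and the SD and 5-point limits below were chosen after seeing the data. No paired analysis was possible because each group had 1 array. A list median or gene moved if it shifted by more than the typical SD between probe sets of a gene (0.31 to 0.32 on the log2 scale), and an absent share if it shifted by more than 5 points. Arrays are compared without detection calls, so signal near background limits the folds of dim genes. Over all settings, 809 list medians stayed within that SD, 207 moved and 2 turned, and 3704 values of genes stayed, 1310 moved and 23 turned. A value turned if it changed sign and had been at least 1 in size on the log2 scale. Sign changes of smaller values count as stayed or moved. Among them was the endothelial median in depleted against wild type lung, at 0.14 and at -1.15 with equal control medians. Median or quantile scaling, the median over probe sets, leaving out probe sets of shared sequence, no level filter and the floor left all 6 gene counts within 1.5 times. The cause of the shifts below was not tested, except that stricter thresholds and filters count fewer genes and probe set counts are not limited to named genes.

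In the order tumour against wild type, depleted against tumour and depleted against wild type, counts at 3-fold were 652 higher and 587 lower, 390 and 425, and 351 and 221. Counts of probe sets were 2260 and 2541, 1861 and 1759, and 1502 and 1525. The 75th percentile filter gave 696 higher in the first, 492 lower in the second and 323 lower in the third. At 1.5-fold 904 were lower in the third, and the authors' deposited table had 1660 probe sets lower in the first. Equal medians of the hybridization controls, a shift of 1.13, 0.16 and 1.29, moved the median of all probe sets to -1.17, -0.13 and -1.31 and gave 422 higher in the first, and 152 higher and 1561 lower in the third. The median control difference from wild type, a shift of 1.00, 0.18 and 1.18, moved it to -1.04, -0.16 and -1.20 and gave 463, 174 and 1487. The share of higher among counted genes went from 49.6% to 22.4% and 24.5% in the first and from 54.1% to 8.87% and 10.5% in the third.

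The squamous median in the first was 5.02 with the 75th percentile filter, 3.92 with the floor, 3.17 with equal control medians, 3.30 with the median control difference removed and 3.49 from the authors' deposited table. In the second it was -4.77 with the median over probe sets, -4.98, -3.87 and -3.59 with that filter, the floor and that table. In the third it was -0.11 with no filter and -1.87 and -1.76 with the control scalings in that order. The macrophage median with them was 2.04 and 2.17 in the first and 0.47 and 0.57 in the third. The absent share of higher genes was 61.9% on another probe set, and with equal control medians the shares were 100.1% and 32.5%, and with the median control difference removed 97.5% and 33.1%.

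Only values at least 2-fold apart before the change of setting are listed here, and smaller ones also changed sign. With equal control medians, the first comparison turned negative for the alveolar macrophage (-0.027) and NF-kB (-0.11) lists, Camp (-0.049), Gadd45a (-0.12), Gclc (-0.043), Hmox1 (-0.088), Lox (-0.092), Nfkb2 (-0.11) and Nfkbie (-0.12), and the third for Adgre1 (-0.12), Ctsb (-0.076), Krtdap (-0.063) and Plin2 (-0.28). With the median control difference removed, Adgre1 (-0.018) and Plin2 (-0.17) also turned, while the others named here stayed positive, from 0.010 to 0.10. With the floor, Dhrs7c, Myl3 and Pck1 were at -0.022 in the second, and Krt14 and Krt17 at 0.010 in the third. In the authors' deposited table Myl3 was at -0.15 in the second, and Krtdap at -0.093, Mmp13 at 0.027 and Sprr2h at -0.070 in the third.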

Other observations

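Adipose genes were lower in both mutant lung samples than in the 1 wild type sample. How much fat or heart muscle each sample held was not measured, so mouse and sampling cannot be told apart. All 5 measured adipose genes were at least 2-fold lower in tumour than in wild type lung, and 4 of 5 in depleted lung. The median log2 difference was -5.07 in tumour lung (-3.50 with dim values raised) and -2.43 in depleted lung (-2.13 with dim values raised). In the authors' deposited table all 5 were lower in both, with smaller medians of -1.82 and -0.91. Cfd, the adipocyte protease adipsin, had intensities of 2423, 9.58 and 450 in wild type, tumour and depleted lung. Adipoq, the adiponectin gene, read 979, 35.3 and 141. Cfd and Adipoq were below the tumour array's 25th percentile of 35.5. The atrial peptide gene Nppa read 2002, 34.6 and 83.6, and was 24.0-fold lower in depleted than in wild type lung.

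Of 12 oxidative stress and NADPH oxidase genes 9 were at least 2-fold higher and 3 lower in tumour lung, and in depleted against tumour lung none was 2-fold higher, 3 were lower and 9 were under 2-fold. The median in tumour lung of 1.42 was 0.29 with equal medians of the hybridization controls and 0.42 with the median control difference removed. Ncf4, an oxidase subunit, read 713, 3282 and 2942 in wild type, tumour and depleted lung, and Sod3, an extracellular superoxide dismutase, read 2813, 984 and 465. Of 11 NF-kB genes 9 were at least 2-fold higher and none lower in depleted than in wild type lung, and 7 were higher in tumour than in wild type lung. With these scalings the median of 1.43 in depleted lung was 0.14 and 0.25, and that of 1.02 in tumour lung -0.11 and 0.018. Nfkbie, an inhibitor of NF-kB, read 311, 626 and 1653. The plasma cell gene Jchain read 1145, 11665 and 5102, while the B cell gene Ms4a1 read 705, 389 and 1992.

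Loricrin (Lor) was dim on all arrays, with intensities of 7.87, 78.8 and 55.7. Of 14 housekeeping genes only 2, Gusb and Pgk1, were named, and naming required a 2-fold difference in some comparison, so they do not stand for the list. Both were at least 2-fold higher in tumour than in wild type lung. Their median log2 difference was 1.80 (0.67 and 0.80 when scaled to the hybridization controls in the same order).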
